A study of Mus musculus with 30 samples.

How the data were processed

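The data are bulk RNA-seq of mouse pancreatic islet cells isolated by fluorescence-activated sorting, 30 libraries in 5 groups (alpha n = 8, alpha DT n = 4, alpha Pdx1 n = 5, alpha Pdx1 DT n = 6, beta n = 7). RNA was extracted with a micro column kit and reverse transcribed, per the labels. Reads were aligned with GSNAP to GRCm38, per the submitters' processing notes, and the aligner version, the annotation and the counting rule were not given in the sources used here. The authors deposited a table of quantile-normalized log2 values for 17775 genes, with common quartiles of 5.95, 8.55 and 10.37 in the libraries. Of the names, 137 are numbers and 23 of these are spreadsheet date numbers, which were kept under those names. The planned count tests did not apply to log2 values, so the route written for normalized values before the data were examined was used. Raw reads were not analysed here.

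Genes with a value of at least 5 in at least 4 libraries were tested, which kept 16633 and removed 1142. A linear model with 1 mean per group was fitted to the 30 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes variances. Contrasts compared beta with alpha, alpha DT with alpha, alpha Pdx1 with alpha, alpha Pdx1 DT with alpha Pdx1, alpha DT, alpha and beta, and the effect of the toxin with and without Pdx1 (interaction). P-values were two-sided and adjusted by the Benjamini-Hochberg method over genes within each contrast, with a threshold of 0.05. Lists of marker and pathway genes, 25 in all, were written from general knowledge before the data were examined and tested with camera at its preset correlation, with camera at an estimated correlation and with fry, adjusted over lists within each contrast. Some members of these lists are not reported here by name.

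The position of a library between alpha and beta was the slope of its log2 difference from the alpha libraries of even number on the difference between beta and the alpha libraries of odd number, over genes past the threshold with an absolute log2 fold change of at least 1. List scores are means over list members in a library. Groups were compared with two-sided exact permutation tests, and adjusted p-values for positions were added after the values were seen. Each pair of libraries was compared by a chi-square over genes with a mean value between 4 and 6.5, with the rank of each distinct value in a library taken as its number of reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

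Named genes followed a rule set before the data were examined: a fixed set of hormone, identity, Smo and Insr genes, the 6 highest and 6 lowest fold changes among genes past the threshold that were above the median level in the higher group and on the same side in every library of the first group (3 and 3 for the interaction), and up to 2 risers and 2 fallers per list, or up to 2 members where none passed. Genes named outside this rule are said to be so where they appear.

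The tests were checked on simulated data with the group sizes and residual spread of the real libraries, in which genes vary independently. In each contrast 200 of 16633 genes were changed, 50 at each size. They were drawn only from genes above a set mean value, so recovery of genes at low values was not simulated. Limma recovered 33, 28, 36, 29, 24, 32, 37 and 20 of 50 genes at a log2 fold change of 1 in the contrasts in the order beta, alpha DT and alpha Pdx1 against alpha, then alpha Pdx1 DT against alpha Pdx1, alpha DT, alpha and beta, then the interaction. At 2 it recovered 47, 47, 48, 50, 48, 47, 44 and 43, all in the right direction, and made 6, 14, 14, 12, 9, 13, 15 and 6 false calls. Camera called 0 of 20 unshifted lists and 20 of 20 lists shifted by 0.5 in alpha Pdx1 against alpha. A simulated position of 0.3 was estimated as 0.267 and one of 0 as 0.000189 over 3413 genes. Pairs of libraries simulated over 3000 genes gave 1.96 for the same RNA with reads counted in pairs. RNA with a modest difference gave 1.97, but with reads counted singly, where the same RNA gave 1.01. A difference with reads counted in pairs and a mix of single and paired counts were not simulated, so a value near 2 is not shown to separate these cases. Covariates of Rn18s-rs5 and of the leukocyte list mean were added after the data were seen. Alternatives covered filters, pseudocounts, covariates, library weights, rescaling, a test against a fold change, fits of single contrasts and leaving out libraries.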

Results

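The deposited table held expression values for 17775 genes in 30 bulk RNA-seq libraries of mouse islet cells sorted by fluorescence, in 5 groups. Mature alpha-cells carrying Glucagon-Venus gave 8 libraries (alpha), and the same reporter with RIP-DTR gave 4 libraries taken 30 days after diphtheria toxin (alpha DT). Alpha-cells made to express Pdx1 through Glucagon-rtTA, TetO-Cre, a YFP reporter and CAG-Pdx1 gave 5 libraries (alpha Pdx1), and 6 more came from mice that also carried RIP-DTR and received the toxin (alpha Pdx1 DT). Insulin-mCherry beta-cells gave 7 libraries (beta). The comparisons address how loss of beta-cells, Pdx1 and their combination change gene expression in glucagon-producing cells. Values were quantile-normalized log2 values, so the most abundant genes of every library took fixed values, such as 20.54, 19.87 and 19.27 for the genes after the top gene. Fold changes of the hormone genes therefore show changes of rank and not of amount. Read numbers were not in the table, and the number of distinct values below the common first quartile, which grows with depth, ran from 32 in the library labelled alpha Pdx1 DT 6 to 111 in the library labelled alpha 8. The labels do not say that the libraries come from separate animals, so each p-value measures only the spread between these samples. Errors after ± are standard errors of log2 fold changes, p-values are adjusted over the 16633 genes tested in the linear models of limma, and SD is the spread between libraries.

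Pdx1 (GRCm38 chr5:147269959-147275848), the homeodomain factor of beta-cell identity introduced by the transgene, had a mean log2 value of 5.54 (SD 2.44, n = 8) in alpha, 5.64 (SD 1.37, n = 4) in alpha DT, 10.89 (SD 1.34, n = 5) in alpha Pdx1, 10.80 (SD 2.62, n = 6) in alpha Pdx1 DT and 11.20 (SD 0.48, n = 7) in beta. In the libraries labelled alpha 1 to 8 it was 3.68, 5.56, 4.51, 5.61, 4.43, 3.66, 5.60 and 11.23. In those labelled alpha DT 1 to 4 it was 6.52, 6.70, 3.71 and 5.63, and in those labelled alpha Pdx1 1 to 5 it was 11.6, 10.78, 11.83, 11.64 and 8.61. The libraries labelled alpha Pdx1 DT 1 to 6 had 11.87, 12.59, 11.53, 11.64, 5.51 and 11.66, and those labelled beta 1 to 7 had 10.45, 11.42, 11.26, 11.66, 10.78, 11.07 and 11.77. The library labelled alpha 8 thus had Pdx1 at the level of the Pdx1 groups, and the library labelled alpha Pdx1 DT 5 at the level of alpha. Ttr, a transthyretin abundant in alpha-cells, was 16.98 in the library labelled alpha 8, and 20.54 in the libraries labelled alpha Pdx1 DT 5 and alpha Pdx1 5. The libraries labelled alpha 4 and alpha Pdx1 DT 5 correlated at 0.993 over genes, and their low-level values differed by a chi-square of 2.02 per degree of freedom over 3187 genes. The next lowest of the 435 pairs of libraries had 3.92 and the median within groups was 18.7. Reads counted only in pairs give about 2 for repeated sampling of the same RNA. Single counts occurred too, as alpha 4 had 49 genes at the first value above its lowest and 120 at the second. The value for the same RNA in such a mix was not simulated. This pair may hold the same RNA under both labels, which 2.02 does not settle. The libraries are not identical, with 79 distinct values below the common first quartile in alpha 4 and 63 in alpha Pdx1 DT 5. In the libraries labelled beta 1 and beta 5, Gcg was the most abundant gene. All comparisons use the libraries under their deposited labels, and each count of genes that differ between 2 groups is given again without the 5 libraries alpha 8, alpha Pdx1 5, alpha Pdx1 DT 5, beta 1 and beta 5. These were picked by their Pdx1 and Gcg levels, so values without them describe the other libraries and do not test Pdx1, hormone or identity genes anew.

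**Figure D1:**
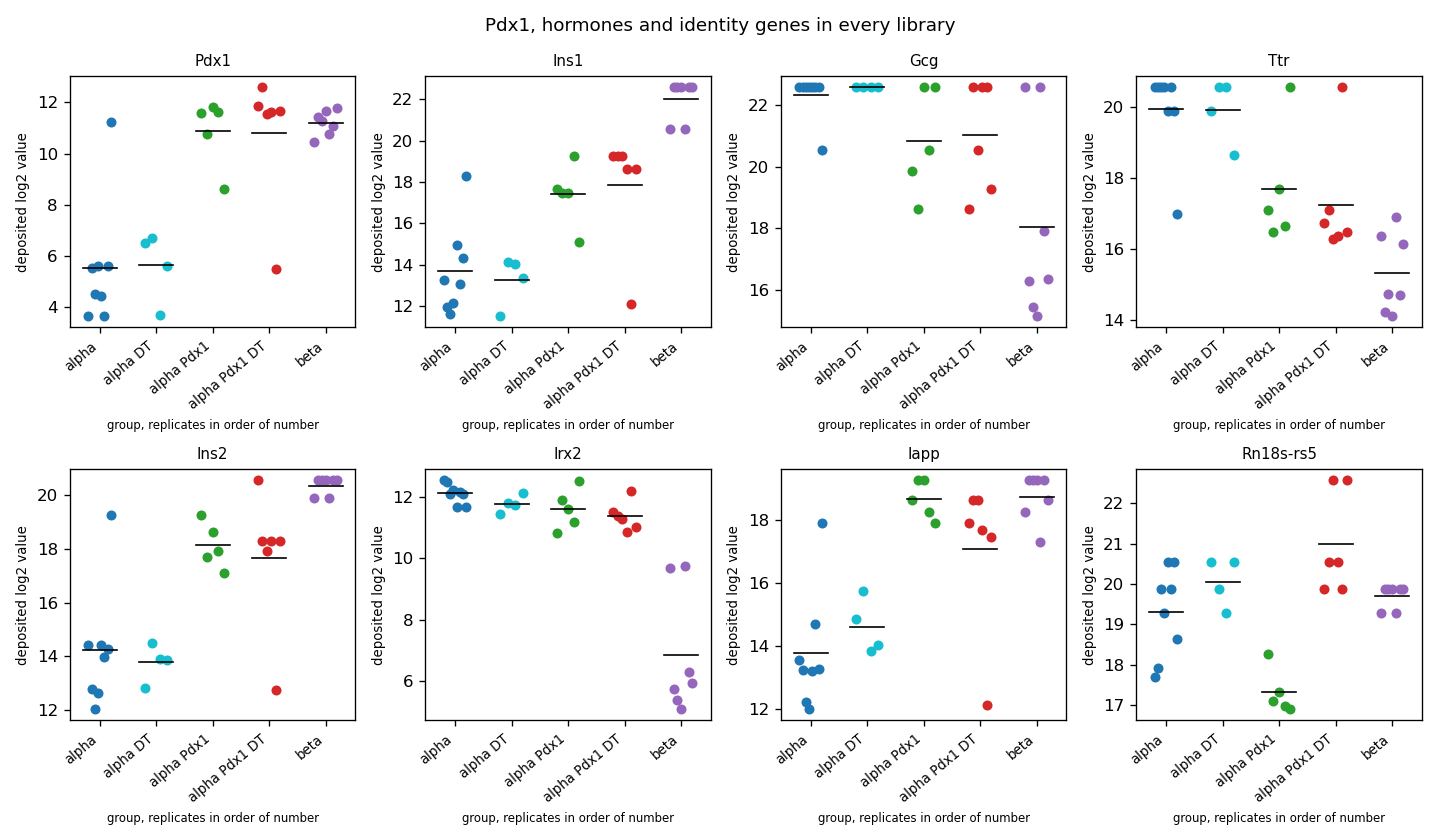
Deposited log2 values of Pdx1, hormone, identity and ribosomal RNA genes in each of the 30 libraries by group. Horizontal lines are group means.

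Mature beta-cells (n = 7) and alpha-cells (n = 8) differed in the hormones, transcription factors and receptors that define them. The glucose transporter gene Slc2a2 was higher in beta by 8.40 ± 0.47 (adjusted p = 1.48e-14), the peptide gene Ucn3 by 8.53 ± 0.76, the cation channel gene Trpm5 by 8.43 ± 0.62 and the incretin receptor gene Glp1r by 8.35 ± 0.55. Ins1 (chr19:52264297-52265476) was higher by 8.29 ± 0.99, the nucleotide receptor gene P2ry6 by 8.11 ± 0.77 and Pdx1 by 5.67 ± 0.97 (adjusted p = 4.88e-05). Lower in beta were the alpha-cell factor genes Irx1 (-5.41 ± 0.58) and Irx2 (-5.28 ± 0.53), the vasopressin receptor gene Avpr1b (-5.49 ± 0.77), the hypoxia-induced gene Higd1a (-5.47 ± 0.54) and Vwde (-5.39 ± 0.50). In total 5734 genes differed, 2804 higher and 2930 lower in beta (5293 without the 5 libraries). A total of 1076 genes passed a test against an absolute log2 fold change of 1.

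Of the 24 measured beta-cell identity genes, 23 rose in beta and none fell (23 adjusted over the list alone; list adjusted p = 2.32e-28). Among them were Prlr, a prolactin receptor (7.75 ± 0.42), Hadh, a mitochondrial fatty acid enzyme (6.08 ± 0.33), Nkx6-1 (5.62 ± 0.36), Mafa (chr15:75745490-75748228; 6.47 ± 0.47) and Ins2 (6.12 ± 0.88). Of 20 alpha-cell identity genes, 19 fell (19 adjusted over the list alone; list adjusted p = 3.06e-17). Gcg (chr2:62474530-62483650) was at -4.27 ± 1.00 and Etv1 at -4.09 ± 0.36. Immediate early genes, induced within minutes of stimulation or tissue dissociation, fell in 17 of 19 cases (17 adjusted over the list alone; list adjusted p = 8.75e-16). Fos was at -3.64 ± 0.27 and Ier2 at -3.47 ± 0.29. These 3 lists kept their call with an estimated correlation (adjusted p = 0.00585, 0.0385 and 0.0466). Unfolded protein response genes rose in 15 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone; list adjusted p = 1.12e-07, adjusted p = 0.0524 with an estimated correlation). Sel1l (1.33 ± 0.13) and Dnajc3 (1.30 ± 0.15), which act in quality control of secretory proteins, rose, and the stress factor gene Atf3 was at -4.50 ± 0.54. Glycolysis genes rose in 6 of 16 cases and fell in 1 (7 and 1 adjusted over the list alone; list adjusted p = 0.0162, adjusted p = 0.658 with an estimated correlation). Pkm was at 1.34 ± 0.19, Pgk1 at 1.01 ± 0.19 and Hk1 at -2.58 ± 0.31. Of 17 genes kept low in beta-cells (disallowed genes), 7 fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.0148, adjusted p = 0.678 with an estimated correlation). Oat was at -3.04 ± 0.33 and Cat at 1.38 ± 0.45.

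Insulin signalling genes moved both ways, 13 rising and 3 falling of 31 (13 and 4 adjusted over the list alone; list adjusted p = 0.108). Igf1r was at 1.81 ± 0.22, Grb10 at -2.51 ± 0.28 and the insulin receptor gene Insr at 0.22 ± 0.13 (adjusted p = 0.195). The Hedgehog list had 3 rises and 3 falls among 13 (3 and 3 adjusted over the list alone). The signal transducer gene Smo was at -1.65 ± 0.31, Gli2 at -3.20 ± 0.54 and Cdon at 0.72 ± 0.13. Excitability genes rose in 9 and fell in 5 of 26 cases (9 and 5 adjusted over the list alone). The glucagon receptor gene Gcgr was at 7.50 ± 0.59 and the somatostatin receptor gene Sstr2 at -3.69 ± 0.47. Interferon response genes rose in 7 and fell in 1 of 19 cases (7 and 1 adjusted over the list alone). Oas2 rose by 4.25 ± 0.67. Mesenchymal genes fell in 3 of 6 cases (4 adjusted over the list alone; list adjusted p = 0.0286, adjusted p = 0.658 with an estimated correlation). Col1a2 was at -4.23 ± 0.36. The pancreatic polypeptide gene Ppy was at -3.10 ± 0.66 and Pyy at -4.02 ± 0.94. Sst, the delta-cell hormone, was at -1.13 ± 0.79 (adjusted p = 0.289), and at -2.59 (adjusted p = 0.00563) without the 5 libraries. No acinar-cell gene passed the test among 16, with Clps at 1.39 ± 1.70 (adjusted p = 0.562).

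In alpha DT (n = 4) against alpha (n = 8) 3 of 10 leukocyte and macrophage genes rose (5 adjusted over the list alone; list adjusted p = 1.17e-06). The list had adjusted p = 0.842 with an estimated correlation and its mean an adjusted exact p of 0.0606. Timd4 (chr11:46810800-46844332), a phosphatidylserine receptor of resident macrophages, rose by 5.71 ± 1.06 (adjusted p = 0.00368), the scavenger receptor gene Marco (chr1:120474538-120505024) by 5.17 ± 1.26, the nuclease gene Dnase1l3 by 4.96 ± 1.29 and the lysozyme gene Lyz2 by 4.85 ± 1.35. The colony-stimulating factor receptor gene Csf1r (chr18:61100598-61132149) rose by 4.38 ± 1.04 and Tyrobp by 4.90 ± 1.08. The neuropeptide genes Vip (5.66 ± 0.95, adjusted p = 0.00158) and Npy (4.51 ± 0.88) also rose. Lower were Kcnn2, a calcium-activated potassium channel, at -2.64 ± 0.43 (adjusted p = 0.00122), Cntnap5b at -2.35 ± 0.48, the fatty acid receptor gene Ffar2 at -1.88 ± 0.29, Rgs16 at -1.82 ± 0.39, Mrpl41 at -1.69 ± 0.28 and Upk3a at -4.43 ± 1.09 (adjusted p = 0.0243).

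The 16 acinar-cell genes had a list adjusted p of 0.0248 with none past the test alone (adjusted p = 0.842 with an estimated correlation), and the delta-cell gene Sst was at 2.12 ± 0.94 (adjusted p = 0.204). Ppy was at 2.12 ± 0.79 (adjusted p = 0.128), and rose by 2.32 (adjusted p = 0.00284) without the 5 libraries. In the beta-cell identity list 2 of 24 genes rose, Npy and Hadh (1.39 ± 0.39), and no alpha-cell identity gene passed the test. Gcg took the top value in every alpha DT library (SD 0) and in each alpha library except alpha 8, so it could not rise, and its difference of 0.25 ± 1.18 (adjusted p = 0.932) came from alpha 8. Ins1 was at -0.43 ± 1.17 (adjusted p = 0.871), Ins2 at -0.45 ± 1.04 (adjusted p = 0.846) and Pdx1 at 0.10 ± 1.15 (adjusted p = 0.972). Smo (-0.10 ± 0.36, adjusted p = 0.911) and Insr (0.26 ± 0.16, adjusted p = 0.365) were not past the test either. Foxo4 (1.88 ± 0.53) and Foxo3 (0.78 ± 0.23), transcription factors restrained by insulin signalling, rose. Nkx2-2, an endocrine factor gene, rose by 1.03 ± 0.25, and Scg3, which sorts secretory granule cargo, had -0.87 ± 0.24. The Notch target gene Hes1 (-2.04 ± 0.57), Notch1 (-0.59 ± 0.16), the chaperone gene Pdia3 (-0.73 ± 0.20), the calcium channel gene Cacna1c (-0.76 ± 0.17), Usp18 (-1.41 ± 0.31) and Atp5a1 (-0.68 ± 0.17) fell. Chac1 (2.34 ± 0.51), Ndrg2 (2.30 ± 0.57), the exocytosis gene Vamp2 (1.38 ± 0.27) and the amino-acid transporter gene Slc38a2 (1.20 ± 0.22) rose.

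In total 543 genes passed, 261 higher and 282 lower in alpha DT (543 without the 5 libraries, of which 417 were shared). A fit of these 12 libraries alone gave 66. The count was 306, 347, 341 or 1078 without the library labelled alpha 2, alpha 4, alpha DT 2 or alpha DT 4. No gene passed a test against an absolute log2 fold change of 1, where 246 had an unadjusted p under 0.05. The count was 295 with Rn18s-rs5 as a covariate and 164 with the leukocyte list mean as a covariate. RIP-DTR differs between the groups along with the toxin. In 13 other fits (filters, offsets, covariates, weights, rescaling, these libraries alone and doubted libraries left out) Pdia3 passed in 5, Foxo3 in 6, Scg3 in 7 and Foxo4, Hes1, Hadh and Lyz2 in 8.

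**Figure D2:**
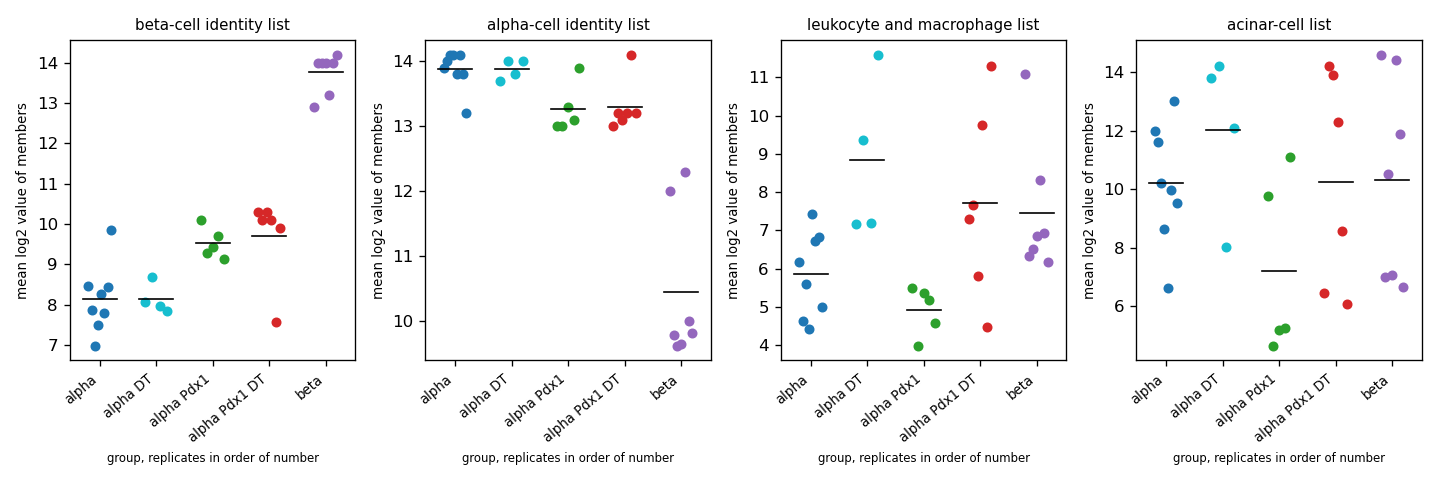
Mean log2 value over the members of 4 gene lists in each library by group. Horizontal lines are group means.

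In alpha Pdx1 (n = 5) against alpha (n = 8) some beta-cell genes rose and others did not pass the test. Pdx1 itself rose by 5.36 ± 1.07 (adjusted p = 0.00604), the islet amyloid gene Iapp (chr6:142298423-142303961) by 4.91 ± 0.89 (adjusted p = 0.00297) and Ins2 (chr7:142678656-142743381) by 3.89 ± 0.97 (adjusted p = 0.0202). Ins1 was at 3.71 ± 1.09 (adjusted p = 0.0524). Mafa (-0.14 ± 0.51, adjusted p = 0.926), Nkx6-1 (-0.40 ± 0.39, adjusted p = 0.664) and Slc2a2 (-0.17 ± 0.52, adjusted p = 0.91) were not past the test. Genes outside the beta-cell list rose as much, namely Lrtm1 (5.04 ± 1.06), the substance P gene Tac1 (4.99 ± 0.90), the neuronal calponin-like gene Tagln3 (chr16:45711230-45724608; 4.95 ± 0.97) and the sodium-glucose cotransporter gene Slc5a1 (4.78 ± 0.98).

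Of the 24 beta-cell identity genes 8 rose (13 rises and 1 fall adjusted over the list alone; list adjusted p = 9.8e-06, adjusted p = 0.7 with an estimated correlation). The beta-cell list includes Pdx1, introduced by the transgene, so part of its rise was set by the design. It was not tested without Pdx1. Of 20 alpha-cell identity genes 2 fell, both amino-acid transporter genes, Slc7a2 (-1.49 ± 0.34) and Slc38a5 (-1.49 ± 0.41). The list had 4 falls adjusted over the list alone (list adjusted p = 0.00543, adjusted p = 0.7 with an estimated correlation). Irx2 (-0.52 ± 0.58, adjusted p = 0.715) and Gcg (-1.48 ± 1.10, adjusted p = 0.541) were not past the test. The gut and islet peptide gene Pyy was at 3.23 ± 1.04 (adjusted p = 0.0771). Secretogranin genes moved both ways, Scg2 at 1.70 ± 0.31 and Scg5 at -0.64 ± 0.18, and Pcsk1n, an inhibitor of prohormone convertase, at -0.89 ± 0.27.

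The chaperone genes Dnajb9 (1.21 ± 0.25) and Dnajc3 (0.59 ± 0.16) rose, 2 of 20 unfolded protein response genes (6 adjusted over the list alone; list adjusted p = 0.0115, adjusted p = 0.7 with an estimated correlation). Of 19 immediate early genes 1 fell, Junb (-1.44 ± 0.37; 1 adjusted over the list alone; list adjusted p = 0.0124, adjusted p = 0.778 with an estimated correlation). The kinase subunit gene Pik3r1 (1.06 ± 0.26) and the adaptor gene Grb14 (0.81 ± 0.22) of insulin signalling rose, as did the sodium channel gene Scn9a (1.11 ± 0.22), the adrenergic receptor gene Adra2a (3.70 ± 1.09) and Ctnnb1 (0.68 ± 0.19). The Notch genes Heyl (-3.49 ± 0.73) and Notch1 (-0.66 ± 0.15) fell. Smo was at -0.08 ± 0.34 (adjusted p = 0.934) and Insr at -0.02 ± 0.14 (adjusted p = 0.967). Among the lowest were Upk3a (-3.79 ± 1.01), the neurotrophic factor receptor gene Gfra3 (-2.30 ± 0.61), Glud-ps (-2.15 ± 0.32), Rpl21-ps11 (-2.26 ± 0.59), Rpl30-ps1 (-2.09 ± 0.44) and Rpsa-ps1 (-2.05 ± 0.53), of which the last 4 are pseudogenes that share sequence with expressed parents. The 16 acinar-cell genes had a median log2 fold change of -3.27 with none past the test (list adjusted p = 3.39e-05, adjusted p = 0.7 with an estimated correlation), and the ribosomal RNA gene Rn18s-rs5 averaged 17.31 (SD 0.56) against 19.29 (SD 1.11) in alpha.

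In total 721 genes passed, 392 higher and 329 lower in alpha Pdx1 (1099 without the 5 libraries, of which 626 were shared), and 1 gene passed a test against an absolute log2 fold change of 1. The count was 447, 328, 452 or 301 without the library labelled alpha 3, alpha Pdx1 2, alpha Pdx1 3 or alpha Pdx1 4. Ins2 lost its call without alpha Pdx1 3 or 4 (adjusted p = 0.0561 or 0.0568). With Rn18s-rs5 as a covariate 114 genes passed, 86 higher and 28 lower, and Ins2 had adjusted p = 0.121. Of 13 other fits Ins1 passed in 6, Pyy in 4 and Irx2 in 1. The reporter strain differs between the groups along with Pdx1.

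In alpha Pdx1 DT (n = 6, among them the library labelled alpha Pdx1 DT 5) some beta-cell genes were higher than in alpha DT (n = 4). Pdx1 rose by 5.16 ± 1.21 (adjusted p = 0.0259), Ins1 by 4.61 ± 1.24 (adjusted p = 0.0487), the glucose-6-phosphatase gene G6pc2 (chr2:69211073-69227841) by 4.22 ± 0.84 (adjusted p = 0.00904) and the fatty acid receptor gene Ffar1 by 3.52 ± 0.60 (adjusted p = 0.00199). Ins2 was at 3.90 ± 1.10 (adjusted p = 0.0604). Tagln3 rose by 5.51 ± 1.09, the defensin gene Defb1 by 3.38 ± 0.88, the calcium release channel gene Ryr3 by 3.18 ± 0.77, Fgl2 by 3.05 ± 0.57 and Scel by 2.98 ± 0.67. The myelin protein gene Pmp22 (-2.30 ± 0.39, adjusted p = 0.0018), Kctd12b (-2.27 ± 0.53), the alcohol dehydrogenase gene Adh1 (-1.58 ± 0.36), Tmsb15b1 (-1.50 ± 0.35), Fam43a (-1.46 ± 0.40) and Tnip2 (-1.45 ± 0.33) fell.

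Of 24 beta-cell identity genes 6 rose (13 adjusted over the list alone, list adjusted p = 5.05e-06, adjusted p = 0.505 with an estimated correlation). Pdx1, introduced by the transgene, is among the 6, so part of this rise was set by the design. None of the 20 alpha-cell identity genes passed the test (2 falls adjusted over the list alone; list adjusted p = 0.0228, adjusted p = 0.868 with an estimated correlation). Ttr was at -2.65 ± 0.86 (adjusted p = 0.104), Mafa at -0.10 ± 0.58 (adjusted p = 0.95), Nkx6-1 at -0.23 ± 0.44 (adjusted p = 0.833) and Slc2a2 at 1.75 ± 0.59 (adjusted p = 0.112). Excitability and exocytosis genes rose in 3 of 26 cases (5 adjusted over the list alone; list adjusted p = 0.0195, adjusted p = 0.464 with an estimated correlation). They included the synaptotagmin gene Syt13 (0.87 ± 0.22) and Cacna1c (0.68 ± 0.18). Hedgehog genes had a list adjusted p of 0.0407 with none past the test and 1 adjusted over the list alone (adjusted p = 0.464 with an estimated correlation), and Smo was at 0.30 ± 0.38 (adjusted p = 0.736). Aqp4, a water channel, rose by 2.65 ± 0.50 and Scg3 by 1.02 ± 0.26, and the glutamine transporter gene Slc1a5 fell with -1.73 ± 0.46. Acinar-cell genes had a median of -1.72 with none past the test (list adjusted p = 0.0228, adjusted p = 0.868 with an estimated correlation) and ductal-cell genes a median of -0.63 (list adjusted p = 0.0407, adjusted p = 0.585 with an estimated correlation).

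In total 349 genes passed, 296 higher and 53 lower in alpha Pdx1 DT (953 without the 5 libraries, 663 higher and 290 lower, of which 338 were shared). No gene passed in a limma fit of these 10 libraries alone, where 1377 had an unadjusted p under 0.05. None passed a test against an absolute log2 fold change of 1, with 245. Leaving out the library labelled alpha DT 3, alpha DT 4, alpha Pdx1 DT 1, alpha Pdx1 DT 2, alpha Pdx1 DT 4, alpha Pdx1 DT 5 or alpha Pdx1 DT 6 gave 138, 599, 183, 197, 181, 930 or 203 genes. Without any of these 10 libraries other than alpha Pdx1 DT 5 Ins1 was no longer past the threshold (adjusted p from 0.0563 to 0.1). Pdx1 lost its call without alpha DT 3 (adjusted p = 0.099) and without alpha Pdx1 DT 1, 2, 4 or 6 (0.0545, 0.0544, 0.0521 or 0.0524). The count was 190 with Rn18s-rs5 as a covariate, where Pdx1 and Ins1 had adjusted p = 0.0615 and 0.111, and 699 with the leukocyte list mean as a covariate. Ins1 passed in 8 of 13 other fits, Ins2 in 4, Slc2a2 in 3 and Ttr in 2, and Slc1a5 in 8 of 12. As without the toxin, the reporter strain differs between the groups along with Pdx1.

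In the groups labelled alpha Pdx1 DT (n = 6) and alpha (n = 8), with alpha Pdx1 DT 5 and alpha 8 under their labels, Pdx1 was higher in alpha Pdx1 DT by 5.26 ± 1.01 (adjusted p = 0.00666), Ins1 by 4.17 ± 1.04 (adjusted p = 0.0182) and Ins2 by 3.45 ± 0.92 (adjusted p = 0.0253). Lrtm1 rose by 3.85 ± 1.00, the zinc transporter gene Slc39a8 by 3.46 ± 0.60 (adjusted p = 0.00459), the potassium channel subunit gene Kcnmb1 by 3.02 ± 0.57, the polysialyltransferase gene St8sia2 by 2.85 ± 0.51, the cadherin gene Cdh4 by 2.53 ± 0.48 and Pld5 by 2.47 ± 0.50. Lower were Corin, a natriuretic peptide convertase (-2.05 ± 0.36, adjusted p = 0.00459), Kctd12b (-1.90 ± 0.44), the pseudogene Eif3s6-ps1 (-1.73 ± 0.46), the monoamine enzyme gene Ddc (-1.72 ± 0.31), Ang (-1.53 ± 0.43) and Rilpl2 (-1.41 ± 0.25).

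Of 24 beta-cell identity genes 10 rose (13 adjusted over the list alone; list adjusted p = 1.94e-07, adjusted p = 0.483 with an estimated correlation). Ffar1 was among them (2.86 ± 0.51), as was Pdx1, introduced by the transgene, so part of this rise was set by the design. Of 20 alpha-cell identity genes 3 fell (3 adjusted over the list alone; list adjusted p = 0.0157, adjusted p = 0.808 with an estimated correlation). Ttr was at -2.68 ± 0.72 and Sphkap at -0.64 ± 0.18. Gcg (-1.29 ± 1.04, adjusted p = 0.451), Mafa (0.03 ± 0.49, adjusted p = 0.978) and Slc2a2 (0.96 ± 0.49, adjusted p = 0.212) were not past the test. Insulin signalling genes rose in 3 of 31 cases (3 adjusted over the list alone; list adjusted p = 0.00578, adjusted p = 0.563 with an estimated correlation). They included Pik3r1 (1.16 ± 0.24) and Foxo1 (0.90 ± 0.22). Insr was at 0.37 ± 0.14 (adjusted p = 0.0824) and Smo at 0.20 ± 0.32 (adjusted p = 0.727). Exocytosis genes rose in 4 of 26 cases (6 adjusted over the list alone; list adjusted p = 0.00578, adjusted p = 0.483 with an estimated correlation). Vamp2 was at 1.25 ± 0.24 and the vesicle GTPase gene Rab3a at 0.96 ± 0.24. Of 30 oxidative phosphorylation genes 4 fell (5 adjusted over the list alone; list adjusted p = 0.0157, adjusted p = 0.808 with an estimated correlation). They included Ndufb10 (-1.06 ± 0.24) and Atp5a1 (-0.59 ± 0.15). Glycolysis genes had a list adjusted p of 0.0118 with none past the test (adjusted p = 0.616 with an estimated correlation).

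The Notch target Hes1 (-2.28 ± 0.50), the prohormone processing gene Cpe (-1.83 ± 0.47), the ductal genes Krt7 (-1.17 ± 0.28) and Prom1 (-0.99 ± 0.28) and Scg5 (-0.58 ± 0.17) fell. The taurine transporter gene Slc6a6 (1.21 ± 0.23), Slc7a5 (0.77 ± 0.23), Tapbp (0.74 ± 0.17), Syvn1 (0.83 ± 0.22), Aqp4 (2.13 ± 0.42) and Scg2 (0.94 ± 0.29) rose. Markers of other cells moved too: of 9 delta-cell genes 1 rose, Efnb3 (1.51 ± 0.37; 1 adjusted over the list alone; list adjusted p = 0.0328), and of 10 leukocyte genes 1 rose, C1qa (1.93 ± 0.56; 1 adjusted over the list alone; list adjusted p = 0.00345). Both lists had adjusted p = 0.616 with an estimated correlation. In total 1299 genes passed, 676 higher and 623 lower (3371 without the 5 libraries, of which 1297 were shared). In a limma fit of the 14 libraries alone none passed, where 3839 had an unadjusted p under 0.05. None passed a test against an absolute log2 fold change of 1, with 302. The count was 814, 804, 785 or 766 without the library labelled alpha 1, alpha 3, alpha 4 or alpha 6. Without the library labelled alpha Pdx1 DT 1, 2, 3, 4, 5 or 6 it was 511, 803, 782, 453, 3487 or 307. Ins1 lost its call without alpha Pdx1 DT 1, 4 or 6 (adjusted p = 0.0514, 0.05 or 0.0562), and Ins2 without alpha 3 or 4 (0.0508 or 0.0501) or alpha Pdx1 DT 1, 2, 4 or 6 (0.0766, 0.0508, 0.0619 or 0.0685). With these 14 libraries fitted alone, Pdx1, Ins1 and Ins2 had adjusted p = 0.0813, 0.11 and 0.145. With Rn18s-rs5 as a covariate no gene passed with limma (1990 with an unadjusted p under 0.05), and Pdx1, Ins1 and Ins2 had adjusted p = 0.147, 0.278 and 0.25. With the leukocyte list mean as a covariate 118 genes passed, and Ins1 and Ins2 had adjusted p = 0.1 and 0.126. Of 13 other fits Slc2a2 passed in 3, with log2 fold changes from 0.87 to 2.01 over all of them, and Insr in 2. Here too the reporter strain differs between the groups, as does RIP-DTR.

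Between alpha Pdx1 DT (n = 6) and alpha Pdx1 (n = 5), under their deposited labels, no difference past the test was found in Pdx1 (-0.10 ± 1.14, adjusted p = 0.969), Ins1 (0.46 ± 1.16, adjusted p = 0.836), Ins2 (-0.45 ± 1.03, adjusted p = 0.821) or Gcg (0.19 ± 1.17, adjusted p = 0.939). Higher after the toxin were the ribosomal RNA gene Rn18s-rs5 (3.68 ± 0.51, adjusted p = 0.000795), Mir5105 (4.10 ± 0.95), the lipoprotein gene Apoe (3.77 ± 1.11), the histone gene Hist1h4d (3.24 ± 0.64), Polr2f (3.22 ± 0.70) and the Wnt agonist gene Rspo4 (3.17 ± 0.46). Rn18s-rs5 was between 16.90 and 18.27 in the alpha Pdx1 libraries and at least 19.87 in those of alpha Pdx1 DT. Lower were Cpe (-2.31 ± 0.53), the early response gene Ier5 (-1.77 ± 0.37), the endothelin receptor gene Ednra (-1.74 ± 0.52), Nsmce4a (-1.72 ± 0.45), Eif1ax (-1.68 ± 0.33) and Uqcrb (-1.68 ± 0.44).

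Of 10 leukocyte and macrophage genes 3 rose (5 adjusted over the list alone; list adjusted p = 7.75e-05, adjusted p = 0.817 with an estimated correlation). They included Csf1r (3.74 ± 1.03) and C1qa (2.93 ± 0.62). The acinar-cell list had a median of 3.21 with no gene past the test (list adjusted p = 0.000731, adjusted p = 0.817 with an estimated correlation). Npy rose by 3.86 ± 0.87, the only 1 of 24 beta-cell identity genes past the test, and Tmem27 (-1.20 ± 0.38) was the only 1 of 20 alpha-cell identity genes. Glycolysis genes rose in 3 of 16 cases (4 adjusted over the list alone; list adjusted p = 0.0348, adjusted p = 0.817 with an estimated correlation). Pkm was at 0.77 ± 0.22 and Aldoc at 0.93 ± 0.29. Oxidative phosphorylation genes fell in 5 and rose in 1 of 30 cases (6 and 2 adjusted over the list alone; list adjusted p = 0.0645). Atp5j was at -1.13 ± 0.28, Ndufa4 at -0.80 ± 0.20 and Cox4i1 at 1.53 ± 0.36. The insulin signalling genes Akt1 (0.97 ± 0.22) and Foxo4 (1.90 ± 0.52) rose and Grb14 (-1.03 ± 0.23) and Sos1 (-0.56 ± 0.17) fell. Insr was at 0.39 ± 0.15 (adjusted p = 0.0972) and Smo at 0.28 ± 0.36 (adjusted p = 0.649). The chaperone gene Dnajb9 (-1.29 ± 0.27) and Creld2 (-1.01 ± 0.30) fell; they were 2 of 3 falls in the unfolded protein response list of 20 (3 adjusted over the list alone; list adjusted p = 0.107). Junb (1.69 ± 0.39), Jund (1.08 ± 0.30), Vamp2 (1.69 ± 0.27), Nkx2-2 (1.17 ± 0.25), Pcsk1n (1.25 ± 0.28), Tapbp (0.94 ± 0.19), Slc38a1 (3.24 ± 1.03), Slc7a5 (0.87 ± 0.25), Notch1 (0.52 ± 0.16) and Smad7 (0.97 ± 0.31) rose. Slc3a1 (-1.12 ± 0.28), Wnt5b (-2.35 ± 0.74) and Bmpr2 (-0.81 ± 0.27) fell.

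In total 1534 genes passed, 804 higher and 730 lower after the toxin (1272 without the 5 libraries, of which 1008 were shared; 2456 without alpha 8 and alpha Pdx1 DT 5). A fit of these 11 libraries alone gave 904, and rescaling by median ratios gave 931 higher and 529 lower. Without the library labelled alpha Pdx1 2, 3, 4 or 5 the count was 671, 968, 798 or 563, and without alpha Pdx1 DT 1, 4, 5 or 6 it was 1006, 976, 2558 or 819. No gene passed a test against an absolute log2 fold change of 1 with limma, where 274 had an unadjusted p under 0.05. With Rn18s-rs5 as a covariate no gene passed with limma either (758 with an unadjusted p under 0.05), and the levels of Rn18s-rs5 do not overlap between these groups. With the leukocyte list mean as a covariate 95 passed. RIP-DTR differs between these groups too, along with the toxin. Of 13 other fits Smad7 passed in 6, Sos1 in 7 and Notch1 and Tmem27 in 8, Insr in 2, and of 12 Wnt5b passed in 6 and Slc38a1 in 7.

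Against mature beta-cells (n = 7), alpha Pdx1 DT (n = 6) had higher alpha-cell genes and lower levels of most beta-cell genes. Slc2a2 was at -7.44 ± 0.51 (adjusted p = 2.41e-12), the granule protein gene Sytl4 at -8.23 ± 0.54, Prlr at -7.87 ± 0.45, Ucn3 at -7.82 ± 0.82, the carbonic anhydrase-related gene Car10 at -7.04 ± 0.61 and Glp1r at -6.94 ± 0.59. Mafa (-6.45 ± 0.50), Nkx6-1 (-5.35 ± 0.38), Ins1 (-4.12 ± 1.07) and Ins2 (-2.67 ± 0.95) were lower too, while Pdx1 was at -0.40 ± 1.05 (adjusted p = 0.825). Higher than in beta were the melanocortin receptor gene Mc4r (7.01 ± 0.85, adjusted p = 3.08e-07), Pyy (6.20 ± 1.01), Pianp (6.08 ± 0.88), Lrtm1 (5.97 ± 1.03) and St8sia2 (5.43 ± 0.52). Irx2 (4.53 ± 0.57), Ppy (4.14 ± 0.71) and Gcg (2.98 ± 1.07, adjusted p = 0.0411) were higher as well.

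Of 24 beta-cell identity genes 18 were lower (20 adjusted over the list alone; list adjusted p = 8.12e-21) and of 20 alpha-cell identity genes 16 were higher (17 adjusted over the list alone; list adjusted p = 3.94e-15). Etv1 (4.05 ± 0.39) was among these. Immediate early genes were higher in 17 of 19 cases (18 adjusted over the list alone; list adjusted p = 4.86e-18). Ier2 was higher by 3.36 ± 0.31 and Btg2 by 1.94 ± 0.17. Unfolded protein response genes were lower in 16 and higher in 1 of 20 cases (16 and 1 adjusted over the list alone; list adjusted p = 6.81e-08). Sel1l was at -1.37 ± 0.14, the asparagine synthetase gene Asns at -1.60 ± 0.21 and Atf3 at 3.56 ± 0.58. These 4 calls held with an estimated correlation (adjusted p = 0.0288, 0.0451, 0.0394 and 0.0473). Disallowed genes were higher in 7 of 17 cases (7 adjusted over the list alone; list adjusted p = 0.00201, adjusted p = 0.521 with an estimated correlation). Hk1 was higher by 3.55 ± 0.34 and Zyx by 1.76 ± 0.28. Mesenchymal genes were higher in 2 of 6 cases (4 adjusted over the list alone; list adjusted p = 0.0155, adjusted p = 0.521 with an estimated correlation). Col1a2 was higher by 5.01 ± 0.39. Smo was higher by 1.85 ± 0.33 and Gli2 by 3.77 ± 0.59. Insr was at 0.15 ± 0.14 (adjusted p = 0.487) with Irs2 at 1.74 ± 0.29 and Igf1r at -0.94 ± 0.24. Sstr2 (2.60 ± 0.50), Scn3a (2.16 ± 0.22) and Fev (3.88 ± 0.50) were higher. Gcgr (-6.28 ± 0.64), Syt13 (-1.29 ± 0.19), Inhba (-2.91 ± 0.69), Oasl2 (-2.14 ± 0.49) and Slc1a4 (-2.86 ± 0.46) were lower. In total 4371 genes differed, 2140 higher and 2231 lower than in beta (4247 without the 5 libraries), and 736 passed a test against an absolute log2 fold change of 1.

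No gene passed the test of whether the toxin acted differently with and without Pdx1 (0 of 16633 with limma, 1527 with an unadjusted p under 0.05, and 1 with library quality weights). The list members nearest the threshold were Notch1 at 1.11 ± 0.22 (adjusted p = 0.158), Heyl at 3.47 ± 1.10 (adjusted p = 0.409), Junb at 1.80 ± 0.55 (adjusted p = 0.409), Akt1 at 0.97 ± 0.31 (adjusted p = 0.409) and Cat at -2.33 ± 0.75 (adjusted p = 0.409). The hormone, transporter and receptor genes named here did not pass, with Ins1 at 0.90 ± 1.65 (adjusted p = 0.896), Slc2a2 at 1.92 ± 0.79 (adjusted p = 0.473), Smo at 0.38 ± 0.51 (adjusted p = 0.85) and Insr at 0.13 ± 0.22 (adjusted p = 0.879). None of the 25 lists was past the list test, the smallest adjusted p being 0.128 for the immediate early and the excitability lists. Without the library labelled alpha DT 1 or alpha DT 2 the count was 3, and the standard errors of Ins1 and Gcg (1.66) leave differences of several log2 units undetected.

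The log2 fold changes of the Pdx1 groups against those without Pdx1 were correlated between mice without and with the toxin. The reporter strain differs along with Pdx1 in both comparisons, so the correlation cannot be assigned to Pdx1 alone. Over 16633 genes, which are not independent replicates, the log2 fold changes of alpha Pdx1 against alpha and of alpha Pdx1 DT against alpha DT, which share no library by label (although alpha 4 in the first and alpha Pdx1 DT 5 in the second nearly repeat each other), correlated at 0.46 (Spearman 0.33), and 59.9% of all genes had the same sign. Of the 721 genes past the threshold in the first comparison 91.8% had the same sign in the second. The 98 genes that rose in both, Pdx1 and Tagln3 among them, compare with 6.98 for independent sets, and the 7 that fell in both with 1.05. No gene passed in opposite directions in both. Without the 5 libraries 323 and 137 genes were shared, with 24.4 and 8.49 for independent sets, and the correlation was 0.56. The effects of the toxin without and with Pdx1 correlated at 0.52 (Spearman 0.45) with the same sign in 67.5% of all genes, and with 92 genes rising in both against 12.6 for independent sets, among them Csf1r, Npy, Nkx2-2 and Vamp2, and 50 falling in both against 12.4. Of the genes past the threshold in both comparisons, 1 had opposite signs. RIP-DTR differs along with the toxin in both comparisons, so this correlation cannot be assigned to the toxin alone. The means of Rn18s-rs5 and of the leukocyte list were also higher in both toxin groups. Of the 296 genes that rose in alpha Pdx1 DT against alpha DT, 125 were higher in beta than in alpha, against 49.9 for independent sets, 32 were lower, against 52.1, and 139 did not differ past the threshold. Of the 53 that fell, 12 were lower in beta, against 9.34 for independent sets, and 11 were higher, against 8.93. Without the 5 libraries, which were picked by Pdx1 and Gcg, 339 of 663 rises were higher in beta, against 106, and of 290 falls 173 were lower, against 45.8, and 18 higher, against 46.5.

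**Figure D3:**
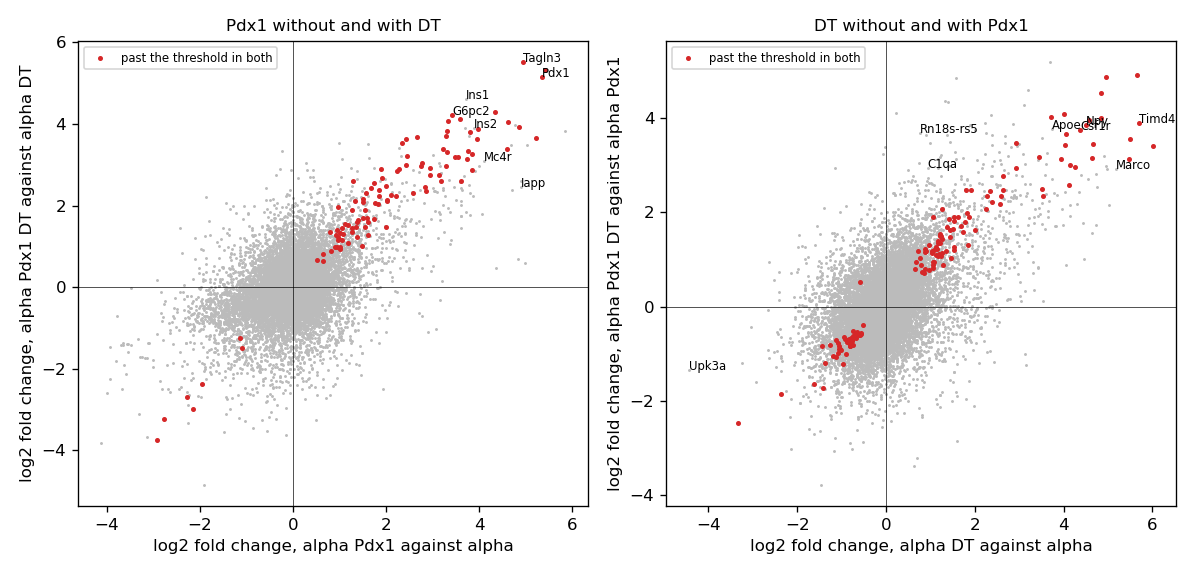
Log2 fold changes of all genes for Pdx1 without and with the toxin (left) and for the toxin without and with Pdx1 (right). Red points passed the threshold in both comparisons.

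On an axis from alpha (0) to beta (1), set by 1609 genes higher in beta and 1608 higher in alpha, each group's position was taken against the alpha libraries of even number (n = 4). Over the beta-cell genes alpha DT lay at 0.0706 (SD 0.0365, n = 4), alpha Pdx1 at 0.168 (SD 0.0428, n = 5) and alpha Pdx1 DT at 0.234 (SD 0.160, n = 6), with exact permutation p of 0.4, 0.0635 and 0.0476 against alpha. Over the alpha-cell genes they lay at 0.0778 (SD 0.0254), 0.139 (SD 0.0706) and 0.190 (SD 0.151), with exact p of 0.2, 0.0476 and 0.0714. None of the 12 tests passed after adjustment, the smallest adjusted p being 0.143. Without the 5 libraries the positions over the beta-cell genes were 0.121, 0.244 and 0.345, and over the alpha-cell genes 0.0769, 0.163 and 0.203, each with an adjusted exact p of 0.0312 against alpha, a change that picking libraries by Pdx1 favours. Alpha Pdx1 DT against alpha Pdx1 then had an adjusted exact p of 0.0312 over the beta-cell genes and 0.0635 over the alpha-cell genes. Without the library labelled alpha Pdx1 DT 5 alone, which itself lay apart on this axis, the positions of alpha Pdx1 DT were 0.299 and 0.250 (adjusted exact p = 0.0159).

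**Figure D4:**
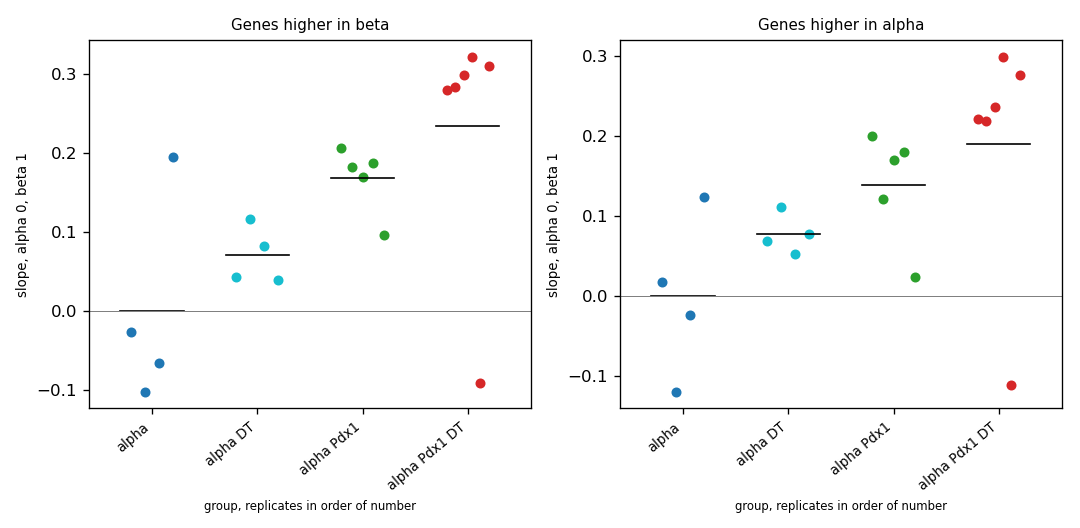
Position of each library on the axis from alpha (0) to beta (1), over genes higher in beta (left) and genes higher in alpha (right). Horizontal lines are group means and alpha is shown by its libraries of even number.

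List means of single libraries were compared by exact permutation tests, 70 in all. The beta-cell identity mean was 13.8 in beta and 8.14 in alpha (exact p = 0.000155, adjusted p = 0.00544), and the alpha-cell identity mean 10.5 and 13.9 (exact p = 0.000155, adjusted p = 0.00544). Beta-cell identity genes averaged 9.53 in alpha Pdx1 (exact p = 0.00932 and adjusted p = 0.0653 against alpha) and 9.71 in alpha Pdx1 DT (exact p = 0.0157, adjusted p = 0.0971), which left them far below beta (exact p = 0.000583, adjusted p = 0.0136). The leukocyte list averaged 8.83 in alpha DT and 5.85 in alpha (exact p = 0.00606, adjusted p = 0.0606), and 7.72 in alpha Pdx1 DT and 4.92 in alpha Pdx1 (exact p = 0.0368, adjusted p = 0.143). The delta-cell list averaged 8.74 in alpha DT and 7.79 in alpha (exact p = 0.00808, adjusted p = 0.0653). The beta-cell identity list includes Pdx1, introduced by the transgene, so part of its rise in the Pdx1 groups was set by the design. In all 5 of the 70 tests passed after adjustment. Without the library labelled alpha 8 or alpha Pdx1 DT 5, which lay apart in identity means themselves, the number was 11 or 16.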

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

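The tests of the Pdx1, Gcg and leukocyte patterns were chosen after the data and these patterns were seen. For the leukocyte pattern the bounds of the correlation and of the Rn18s-rs5 covariate were written before their values were computed, as were those of the splits of the samples, while the leukocyte and mesenchymal list means were known before their difference was tested. In 57 groups of values tested for a library far from the others, 13 had one. The rule has a nominal rate of about 1 in 20 groups, which was not simulated here. All 13 concern the libraries labelled alpha 8 or alpha Pdx1 DT 5, so they are not independent. Gcg took the same top value in the other alpha libraries, so any lower rank would have set alpha 8 apart, and the nominal rate does not apply. The rule uses the gap from 1 library to the next, so libraries apart together, such as beta 1 and beta 5 in Gcg, hide each other. The library labelled alpha 8 lay apart in Pdx1 (11.2), Gcg (20.5), Ins2 (19.3), Ttr (17.0) and the alpha-cell identity mean (13.2). The library labelled alpha Pdx1 DT 5 lay apart in Pdx1 (5.51), Ins1 (12.1), Ins2 (12.8), Ttr (20.5), the beta-cell identity mean (7.57), the alpha-cell identity mean (14.1) and its positions between alpha and beta (-0.0911 over beta-cell genes and -0.111 over alpha-cell genes).

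Pdx1 levels went against the label in these 2 libraries. A swap between them is argued against, since the library labelled alpha 8 lay at 0.26 from alpha Pdx1 (0) to alpha Pdx1 DT (1). The alpha Pdx1 DT libraries, each held out of the fit in turn, lay from 0.63 to 0.909 (SD 0.109), and those of alpha Pdx1 from -0.0618 to 0.474, a comparison added after the value of 0.26 was seen. No test argues against a shared source of the libraries labelled alpha Pdx1 DT 5 and alpha 4. Their chi-square of 2.02 per degree of freedom was the lowest of 435 pairs. The pair may be repeated sampling of the same RNA, although the values of the libraries are not identical. RNA with a modest difference gave a like value in simulated pairs with reads counted singly, and was not simulated with reads counted in pairs. A mix of single and paired counts was not simulated. An animal in which the transgene was silent was not excluded by the bound set, 0.5 of the lowest within-group value. The chi-square of 2.02 was 0.516 of that lowest value, 3.92, which came from a pair of beta libraries. The lowest value within alpha was 10, and the second lowest of alpha Pdx1 DT 5 against alpha was 9.33. Of the other pairs with an alpha library the lowest was 7.19, between the libraries labelled alpha 2 and alpha Pdx1 5. The value of 2.02 lay below all of these. A separate animal with a silent transgene stays open, since a pair of beta libraries reached 3.92 and this comparison was made after the values were seen. From alpha (0) to alpha Pdx1 (1) the library labelled alpha 8 lay at 0.764, and the library labelled alpha Pdx1 5 at 0.652.

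Gcg was the most abundant gene in the libraries labelled beta 1 and beta 5. Gcg expressed by beta-cells without other cell types is argued against by the acinar-cell list, of which 16 of 16 genes were higher in both libraries than in each other beta library, against 11.4% of all genes. Alpha-cells mixed into the libraries stay open, because 15 of 20 alpha-cell identity genes were higher in both, short of the 16 set for this explanation, and 8 of 9 delta-cell and 9 of 10 leukocyte genes were higher too. If alpha-cells were mixed in, the levels of 16 genes would correspond to a median share of alpha-cell RNA of 18.0% in beta 1 (quartiles 13.6% and 26.2%) and 19.3% in beta 5 (16.1% and 32.6%). No biological explanation was tested, since the design names no difference between the beta libraries.

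Of 10 leukocyte and macrophage genes 3 rose in alpha DT against alpha and 3 in alpha Pdx1 DT against alpha Pdx1, while the list had adjusted p = 0.842 and 0.817 with an estimated correlation and its mean adjusted exact p of 0.0606 and 0.143. The leukocyte list rose more than the mesenchymal list in alpha DT, by 3.35 (exact permutation p = 0.00202, the smallest that these groups can give). This does not decide whether a lower share of alpha-cells raised every other type alike. The mesenchymal list was the only one of other cell types that fell (-0.369), and its mean was known before. The others rose, the acinar-cell list by 1.85, endothelial-cell by 1.25, delta-cell by 0.949, PP- and epsilon-cell by 0.819, Schwann-cell by 0.782 and ductal-cell by 0.546. None of these differences was past the threshold after adjustment. Leukocytes among the sorted cells remain a candidate source, as the list members moved together between libraries with group means removed (median correlation 0.729, against 0.0874 at the 95th percentile of 1000 random lists). RNA preparation cannot be told apart from the toxin for these genes. The called members kept a median of 0.886 of their fold change with Rn18s-rs5 as a covariate, which counts against it as the whole cause, but 1 of 3 lost its call, Lyz2, from 4.85 ± 1.35 (adjusted p = 0.0471) to 4.35 ± 1.39 (adjusted p = 0.0984), a lower fold with a like error. Recruitment of macrophages after the loss of beta-cells, which the design would allow, was not tested.

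Of 100 splits of the samples, the real one included, only the real one gave as many genes for beta against alpha (5734, highest other 1672). The same held for alpha DT (543, 460) and alpha Pdx1 (721, 523) against alpha. It also held for alpha Pdx1 DT against alpha Pdx1 (1534, 758) and against beta (4371, 2245). For alpha Pdx1 DT against alpha 2 splits did (1299, 1611). Chance is thus unlikely for these contrasts but not excluded, as the splits are a sample and were not adjusted over contrasts. For alpha Pdx1 DT against alpha DT 6 splits gave as many (349, 1250), so the splits leave chance open. For the interaction the real count was 0, which each of the 100 splits reaches (highest other 3127), so the splits decide nothing. The split with 1250 genes called several times the 349 of the real one, which points to a structure of the samples beyond their labels. Leaving out the library labelled alpha Pdx1 DT 5, whose Pdx1 level goes against its label, gave 930 genes in this contrast. Which libraries the split with 1250 genes moved was not examined.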

How the results depend on the processing

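The tests without 2 or 5 libraries, with library weights, a stricter filter, rescaling or a Y-linked, Rn18s-rs5 or leukocyte covariate were chosen after the data were seen, and the others before the data were examined. Genes past the threshold had the same sign in every other fit except with Rn18s-rs5 as a covariate, where 384 of 1534 genes changed sign in alpha Pdx1 DT against alpha Pdx1. Which direction held more genes changed between fits in most contrasts and is no finding, for example with rescaling in alpha DT (283 higher, 245 lower) and alpha Pdx1 (359, 386) against alpha and in alpha Pdx1 DT against beta (2202, 2161), and in alpha Pdx1 without alpha 1 (455, 530) or alpha 2 (432, 539). Both filters, both pseudocounts, the acinar-cell covariate, rescaling and the Y-linked covariate left each count of genes within 1.5 times its value. A test against an absolute log2 fold change of 1, which asks for more than a difference, gave 1076 genes for beta against alpha, 0 for alpha DT against alpha, 1 for alpha Pdx1 against alpha, 0 for alpha Pdx1 DT against alpha Pdx1, alpha DT or alpha and 736 against beta. Fits of the groups of 1 contrast gave 66 for alpha DT against alpha and 904 for alpha Pdx1 DT against alpha Pdx1. For alpha Pdx1 DT against alpha DT and alpha they gave 0, and the cause was not tested. The main fit shares 1 estimate of spread per gene over all 5 groups. Weights of single libraries ran from 0.238 (alpha Pdx1 DT 6) to 8.07 (beta 6), a lower weight for a wider spread. The main p-values of the alpha groups therefore rest partly on the spread of the beta libraries. Library weights gave, in the order of the report's contrasts with alpha, 9375 (beta), 208 (alpha DT), 3110 (alpha Pdx1) and 3519 (alpha Pdx1 DT). They gave 3769 for alpha Pdx1 DT against alpha Pdx1, 32 against alpha DT, 6881 against beta and 1 for the interaction, and the cause was not tested. With Rn18s-rs5 as a covariate the counts were 295 (alpha DT) and 114 (alpha Pdx1) against alpha, and for alpha Pdx1 DT 0 against alpha Pdx1, 190 against alpha DT and 0 against alpha. With the leukocyte list mean they were 164 (alpha DT against alpha), 95, 699 and 118 (alpha Pdx1 DT against alpha Pdx1, alpha DT and alpha). Both covariates differ between the groups, so they are not separate from the contrasts. The doubted libraries were picked by Pdx1 and Gcg levels, so stronger results without them are no independent tests. Without the libraries labelled alpha 8 and alpha Pdx1 DT 5 the counts were 1115 (alpha Pdx1 against alpha), 2456, 968 and 3472 (alpha Pdx1 DT against alpha Pdx1, alpha DT and alpha). Without all 5 doubted libraries they were 1099, 953 and 3371 for alpha Pdx1 against alpha and alpha Pdx1 DT against alpha DT and alpha. Positions over beta-cell genes without the 2 libraries were 0.135, 0.233 and 0.364, and over alpha-cell genes 0.119, 0.18 and 0.292, each now past the threshold, and without the 5 libraries 0.121, 0.244, 0.345, 0.0769, 0.163 and 0.203. The list-score tests past the threshold rose from 5 to 9 with an offset of 10 and to 18 without the 2 or the 5 libraries, and the list tests fell from 37 to 7 with an estimated correlation. Leaving out 1 library gave 5103 to 5933 genes for beta against alpha, 306 to 1078 for alpha DT, 301 to 985 for alpha Pdx1 and 307 to 3487 for alpha Pdx1 DT. For alpha Pdx1 DT it gave 563 to 2558 against alpha Pdx1, 138 to 930 against alpha DT and 3743 to 4362 against beta, with 0 to 3 for the interaction. Positions then ran from 0.0366 to 0.135, 0.134 to 0.233 and 0.2 to 0.299 over beta-cell genes and from 0.0382 to 0.119, 0.0994 to 0.18 and 0.146 to 0.25 over alpha-cell genes, and list-score tests from 4 to 16. No paired analysis was possible because replicate numbers only follow the order of deposition. Other size factors, library sizes without hormone genes, a second count tool, weights from counts and a filter on scaled counts were not run, since they need counts. Depth is unknown.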

Other observations

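The looks at Lrtm1, at Xist and Y-linked genes, at components and at list-score interactions were chosen after the data were seen. Lrtm1 rose by 5.04 in alpha Pdx1 against alpha and was 5.97 higher in alpha Pdx1 DT than in beta, and it was chosen after its values were seen.

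Xist and Y-linked genes differed between libraries within each group, so the groups mix sexes. The library labelled alpha Pdx1 5 had both Xist (15.69) and Ddx3y (9.95), as did those labelled alpha 6 (13.54 and 10.70), alpha DT 2 (11.85 and 11.13) and beta 6 (16.37 and 9.69), which would occur with pooled animals, and this was not tested. The first 3 principal components held 27.0%, 12.8% and 9.96% of the variance. The list-score interactions of Pdx1 and the toxin had a lowest adjusted exact permutation p of 0.72, for the list of PP- and epsilon-cells with a difference of -1.07.

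The list tests were planned before the data were examined. Lists without a call by camera at its preset correlation in any contrast had smallest adjusted p-values of 0.0679 (PP- and epsilon-cell), 0.122 (interferon response), 0.123 (amino-acid transport), 0.18 (proliferation), 0.239 (antigen presentation), 0.256 (progenitor and dedifferentiation), 0.328 (Schwann-cell), 0.353 (pan-endocrine), 0.391 (Notch, Wnt and TGF-beta signalling) and 0.58 (endothelial-cell, 2 genes measured). By fry, 3 of these lists passed: progenitor and dedifferentiation was lower (adjusted p = 0.00441) and interferon response higher (0.0457) in beta than in alpha, and PP- and epsilon-cell was higher in alpha Pdx1 DT than in beta (0.027).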
